A study of Mus musculus with 6 samples.

How the data were processed

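Gene expression was measured by poly(A)-selected, strand-marking mRNA sequencing in 6 cultures of the mouse embryonic stem cell line Royan B20. Per the labels' protocols, cells grew on 0.1% gelatin and had been passaged 7 times in the R2i medium with LIF, a cytokine that sustains mouse embryonic stem cells. R2i combines 1 µM of a MEK inhibitor, spelled PD0329501 in the labels, with 10 µM SB431542, an inhibitor of TGF-beta, activin and nodal receptors. The labels put 3 libraries in the R2i control group and 3 in the group that also received 250 nM noggin, a secreted BMP antagonist, and 5 µM dorsomorphin, a small-molecule inhibitor of BMP type I receptors. The labels call the 3 libraries of a group biological replicates. They do not state how long the inhibitors were present.

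The authors deposited one table of raw read counts per gene for each library, per the labels and the form of the values, which were whole numbers with different totals in each library. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.4.2, STAR 2.6.1, HTSeq 0.9.1, DESeq2 and the build GRCm38.p6, without giving each tool's role. The annotation release and the strand setting used in counting were not given in the sources used here. Each table held 53465 genes and 5 rows that name no gene. These rows, for reads outside genes, ambiguous reads, unaligned reads and reads with several alignments, took 25.6% to 26.4% of the reads and were left out of library sizes and tests. Reads with several alignments entered no gene's count, so genes with near-identical copies are counted from their distinguishing stretches alone and remain uncertain. Genes with exons overlapping another gene are uncertain as well, including antisense overlaps, since the strand setting is unknown.

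Symbols, coordinates and gene classes were taken from GENCODE release M21 on the same build, which matched 53360 of the 53465 identifiers and left 105 unmatched. Genes were kept with the default filter of edgeR 4.0.16, which asks for a minimum count of 10 scaled to library size and a total of at least 15. The groups were compared with edgeR's quasi-likelihood F test after TMM scaling, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the unshrunk coefficient and its F statistic. Levels are TMM-scaled CPM, counts relative to the library size, given as mean ± SD over 3 libraries. Where all 3 control libraries held 0 counts, the fold was bounded with a floor of 3 counts over the group. With 1 to 3 counts it was given with an exact 95% binomial interval, which covers counting error only.

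Before the data were examined, 37 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took Id1, Id2, Id3, Bmp4, Pou5f1, Sox2 and Nanog whatever their result. It added the 10 largest positive and the 10 largest negative log2 fold changes among called genes with a mean log2 CPM of at least 2, separate groups and a symbol other than a predicted or clone name. From each described list it took up to 4 members with the smallest p; a few genes that this rule names are not reported here. Ribosomal S6 kinases were kept out of the ribosomal protein list. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. This test asks whether a list moved further in one direction than the other genes, and p-values were adjusted over the 37 lists. Each list also has counts of members past the gene test, adjusted over all genes tested and adjusted over the list alone.

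The alternatives were DESeq2 1.42.0, limma-voom, other scalings, other count filters, thinning to the smallest library, smooth offsets over GC content and length with a loess span of 0.3, a replicate block, gene subsets and leaving out each library in turn. For lists, an estimated correlation and the self-contained fry test were added. Near-identical copies were sought with BLAST 2.17.0 among annotated transcripts, at 90% identity or more over at least 50% of the longest transcript. R 4.3.3 and Python 3.11.15 were used.

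The gene test was tested on simulated counts for 15390 genes of this comparison, with 200 genes changed. It recovered 70% of 50 genes changed 1.3-fold, 76% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold. Of its calls, 4.4% were unchanged genes. The simulation used the same dispersion for every gene in either group and changed no low-count genes. Recovery and false calls may therefore differ in these data, where BMP-inhibited replicates varied more and far more genes were called. The list test called the 1 shifted list and 0 of 19 unchanged lists. Simulated genes varied independently of each other, so this cannot show how the list test behaves where members move together. Gene counts totalled 31474666 to 35322844 per library, which gave a median standard error of 0.086 on the log2 scale. Replicates of a group differed by more than sampling noise, with a chi-square per gene of 2.33 to 3.05 between controls and 8.32 to 10.86 between BMP-inhibited libraries, so no pair was treated as 1 library deposited more than once. That they are separate cultures rests on the labels.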

Results

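RNA sequencing libraries were made from mouse embryonic stem cells of the Royan B20 line kept in R2i medium with LIF, where MEK and TGF-beta receptors are inhibited. In 3 libraries this was the only treatment, and in 3 others the BMP inhibitors noggin and dorsomorphin were added. Those are called BMP-inhibited after their labels, which is not a measurement of BMP signalling. Control libraries held 33507205, 35322844 and 32720441 gene counts and BMP-inhibited libraries 31743968, 31474666 and 33774524. Between 22363 and 22849 genes had at least 1 count in a library. The single comparison of the design asks how expression in R2i cells differs when noggin and dorsomorphin are added together. It cannot separate loss of BMP signalling from other effects of these inhibitors.

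Expression differed between the groups for a large part of the transcriptome, in both directions. Of 15951 genes tested, 10236 passed an adjusted p of 0.05 (64.2%), with 5180 higher and 5056 lower in BMP-inhibited cells. The change was at least 2-fold for 2467 genes, 1277 of them higher and 1190 lower, and the median absolute log2 fold change of called genes was 0.54. The groups did not overlap for 10940 genes (68.6%), where chance gives 10%. The first principal component separated the groups and held 82.6% of the variance. Libraries of a group correlated at 0.9914 or above, and libraries of different groups at 0.9591 or below. BMP-inhibited libraries differed more among themselves than controls did, with a chi-square per gene of 8.32 to 10.86 between pairs against 2.33 to 3.05. BMP-inhibited replicate 2 lay apart on the second component (5.5% of the variance), at 27.2 against -20.4 and -4.4 for replicates 1 and 3, and nearer the controls on the first, at 47.6 against 56.9 and 57.7.

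Among named genes with a mean log2 CPM of at least 2 over both groups, the largest rise was that of Tmem92. It had 3 counts in the control libraries together and 789 in the BMP-inhibited ones, a 287-fold ratio (95% counting interval 97.8 to 1390). Tmem92 reached that mean only through the BMP-inhibited libraries. Krt19, a simple-epithelium keratin, rose from 1.36 ± 0.200 to 16.3 ± 3.43 CPM (SD, n = 3; log2 fold change 3.58, SE 0.17). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 3.55 (SE 0.18), and Mep1b, a metalloprotease, by 3.5 (SE 0.16). The imprinted non-coding RNA H19 rose from 14.5 ± 0.554 to 150 ± 20.5 CPM. Parp10, Meis2, Bglap3, H2-Eb1 and Selenoi rose by 3.25, 3.24, 3.21, 3.16 and 3.15 on the log2 scale. Among named genes above the same mean level that fell, Aldh1l2, a mitochondrial folate enzyme, had the largest change at -4.54 (SE 0.14), from 24.7 ± 1.34 to 1.06 ± 0.295 CPM. Derl3, a component of endoplasmic reticulum-associated degradation, fell from 152 ± 1.69 to 7.40 ± 1.24 CPM (log2 fold change -4.36, SE 0.08, adjusted p = 8.07e-15). B4galnt2, Serpinf1, Ubap1l and C1qtnf1 had log2 fold changes of -4.04, -4.00, -3.68 and -3.38. G0s2, Angptl6, Trim66 and Zfp629 followed at -3.29, -3.14, -3.13 and -3.12. H19 and Parp10 overlap another gene's exons on the same strand, and Aldh1l2, B4galnt2, C1qtnf1 and Angptl6 overlap an antisense gene, so their counts are uncertain. On GRCm38, Tmem92 (ENSMUSG00000075610) lies on chromosome 11 at 94777217 to 94782703, and Derl3 (ENSMUSG00000009092) on chromosome 10 at 75893413 to 75895941.

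Genes that BMP-SMAD signalling is known to activate were higher, not lower, in cells with BMP inhibitors. Id1 (ENSMUSG00000042745, chromosome 2, 152736251 to 152737410), a direct SMAD target that encodes an inhibitor of differentiation, rose from 1.71 ± 0.366 to 7.38 ± 1.11 CPM (SD, n = 3), a log2 fold change of 2.11 (SE 0.18, adjusted p = 7.11e-08). Id2 rose from 18.99 ± 1.38 to 36.5 ± 1.69 CPM, by 0.94 (SE 0.07). Id3 was at 30.9 ± 0.677 and 35.7 ± 4.64 CPM, a log2 fold change of 0.21 (SE 0.08, adjusted p = 0.0322). Of the 14 tested members of the target list 11 rose and 0 fell, and 12 rose when adjusted over the list alone. Gata3, Dlx3 and Gata2, transcription factors that also act in trophectoderm, rose by 2.73, 3.08 and 1.86. The list's median was 0.92 (camera adjusted p = 0.00043; adjusted p = 0.18 with an estimated correlation). The Id3 call was lost with library totals only (log2 fold change 0.151, adjusted p = 0.127), without control replicate 1, 2 or 3 (log2 fold changes 0.191, 0.199 and 0.218, adjusted p = 0.107, 0.101 and 0.0717) and without BMP-inhibited replicate 2, where the log2 fold change was 0.102 (adjusted p = 0.151). Gata3 overlaps another gene's exons on the same strand.

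**Figure D1:**
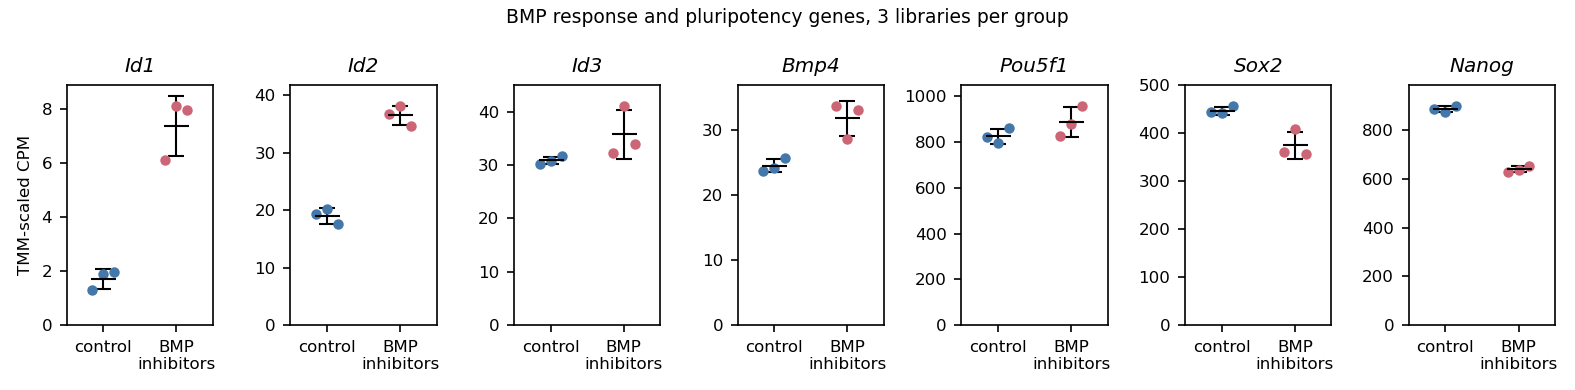
TMM-scaled counts (CPM, linear axes from 0) of Id1, Id2, Id3, Bmp4, Pou5f1, Sox2 and Nanog in control and BMP-inhibited libraries. Points are libraries and black bars are mean ± SD over 3 libraries; Id1 rose from 1.71 to 7.38 CPM, and Nanog fell from 887 to 640 CPM.

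Components of the BMP pathway moved in both directions. Bmp4 (ENSMUSG00000021835, chromosome 14, 46383520 to 46390669), the ligand in the study's title, was at 24.5 ± 1.03 CPM in control and 31.8 ± 2.74 CPM in BMP-inhibited cells, a log2 fold change of 0.37 (SE 0.07, adjusted p = 0.000389). The receptors Bmpr1a and Acvr2b rose by 0.42 and 0.62, and the extracellular regulator Twsg1 by 0.43, while the ligand gene Gdf3 had a log2 fold change of -0.50. Of 25 tested components 12 rose and 5 fell, and the list did not pass (median 0.18, camera adjusted p = 0.20). Bmp4 and Bmpr1a overlap antisense genes. For 29 of the 37 lists, this one included, the counts adjusted over the list alone were the same, and the other 8 are given with both counts.

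Core pluripotency genes stayed abundant and changed by less than 2-fold. Pou5f1, which encodes OCT4, was at 825 ± 32.8 and 887 ± 65.3 CPM, and did not pass (log2 fold change 0.10, SE 0.05, adjusted p = 0.0809). It passed without BMP-inhibited replicate 1 (adjusted p = 0.00593) and with no count filter (0.0364). Sox2 and Nanog fell, with log2 fold changes of -0.25 (SE 0.05) and -0.47 (SE 0.04). Of 16 general pluripotency genes 6 rose and 7 fell, Utf1, Dppa5a and Dppa2 rising by 0.87, 0.83 and 0.75 (camera adjusted p = 0.85). The naive list held 6 risers and 12 fallers among 21 genes, with 13 fallers adjusted over the list alone. In it Klf4, Fgf4 and Tcl1 had log2 fold changes of -0.81, -0.76 and -0.75, while Dppa3, a maternal factor that protects DNA methylation marks, rose by 2.31 (median -0.15, camera adjusted p = 0.20). Formative and primed genes split into 9 higher and 6 lower of 18 (camera adjusted p = 0.35), with Lef1 and Etv4 higher by 2.38 and 0.95 and Sox4 at -1.16. Lef1, Sox4 and Pou5f1 overlap antisense genes.

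The list with the smallest camera p at the preset correlation was that of genes marking the 2-cell-like state. This is a transient state of stem cells that resembles the cleavage-stage embryo. Of 22 members 18 passed the count filter, and all 18 rose, each at least 2-fold. Members with few or no control counts could pass this filter only through high counts in BMP-inhibited cells. They could not have been seen as unchanged or lower. Zscan4c, of a family of zinc-finger genes used to mark this state, had 0 counts in the control libraries and 703 in the BMP-inhibited ones, at least 256-fold higher. Zscan4d had 2 and 717 counts, a 391-fold ratio (95% counting interval 108 to 3240), and Zscan4a 2 and 719. Summed over 9 Zscan4 genes and pseudogenes, counts went from 4 to 4429, with 36.7 to 52.7 CPM in each BMP-inhibited library. Duxf3, which encodes the transcription factor DUX and was chosen after its value was seen, had 0 and 71 counts, at least 25.8-fold higher. The list's median log2 fold change was 6.45 with such genes at their bound (camera adjusted p = 1.1e-10; adjusted p = 0.18 with an estimated correlation). Under the stricter count filter 11 members were tested as higher. Most members have near-identical copies, and 4 of the 18 have none.

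Trophectoderm genes rose together as well. Of 18 tested, 15 rose and 0 fell, 11 of them at least 2-fold, with a median of 1.43 (camera adjusted p = 1.2e-06; adjusted p = 0.18 with an estimated correlation). Krt18 and Krt8, keratins of the trophectoderm, rose from 12.03 ± 0.799 to 78.3 ± 11.8 CPM and from 18.2 ± 0.807 to 89.96 ± 15.7 CPM. Fgfr2 rose by 2.51 (SE 0.09). Primitive streak and mesoderm genes had 8 risers and 1 faller among 14 (median 0.71, camera adjusted p = 0.027; adjusted p = 0.18 with an estimated correlation). Hand1 rose from 0.0959 ± 0.0310 to 6.07 ± 1.22 CPM, and Evx1, Mesp2 and Kdr rose by 4.62, 1.87 and 2.88 from levels under 1 CPM. Hand1 and Eomes are on the trophectoderm list as well, so the 2 lists are not independent. Without them, a test chosen after the results were seen, 7 of 12 mesoderm genes rose and 1 fell, with a median of 0.71, and the list did not pass (adjusted p = 0.057). Of the full mesoderm list, 5 genes rose and 0 fell under the stricter count filter, and 2 fell with limma-voom, with library totals only, with no count filter, without control replicate 2 and without BMP-inhibited replicate 2. Endoderm genes had 10 higher and 4 lower of 20 (camera adjusted p = 0.27), with Lamb1 and Sparc at 0.72 and 0.37 and Lama1 and Sox7 at -1.59 and -1.08. Neuroectoderm genes had 4 higher and 5 lower of 12 (camera adjusted p = 0.97), including Neurod1 at 1.79 and Ncam1, Msi1 and Stmn2 at -1.07, -1.09 and -0.58. Their median was -0.02 and their mean 0.08. Fgfr2, Gata3 and Neurod1 overlap other genes on the same strand, and Krt8, Evx1 and Ncam1 overlap antisense genes.

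Most germline genes fell. Of 22 tested, 15 fell and 4 rose (median -0.44, camera adjusted p = 0.019; adjusted p = 0.18 with an estimated correlation). The meiotic genes Zcwpw1 and Syce1 had log2 fold changes of -1.76 and -1.20 and Piwil2, of the piRNA pathway, -1.33, whereas the RNA-binding gene Dazl rose by 1.55. DNA methylation enzymes and cofactors had 8 higher and 2 lower of 14 (camera adjusted p = 0.15), with Dnmt3l, Mbd3 and Tdg at 0.41, 0.51 and 0.45. Without control replicate 2, or BMP-inhibited replicate 1 or 3, 1 of them was lower. Zcwpw1, Dnmt3l and Tdg overlap antisense genes.

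**Figure D2:**
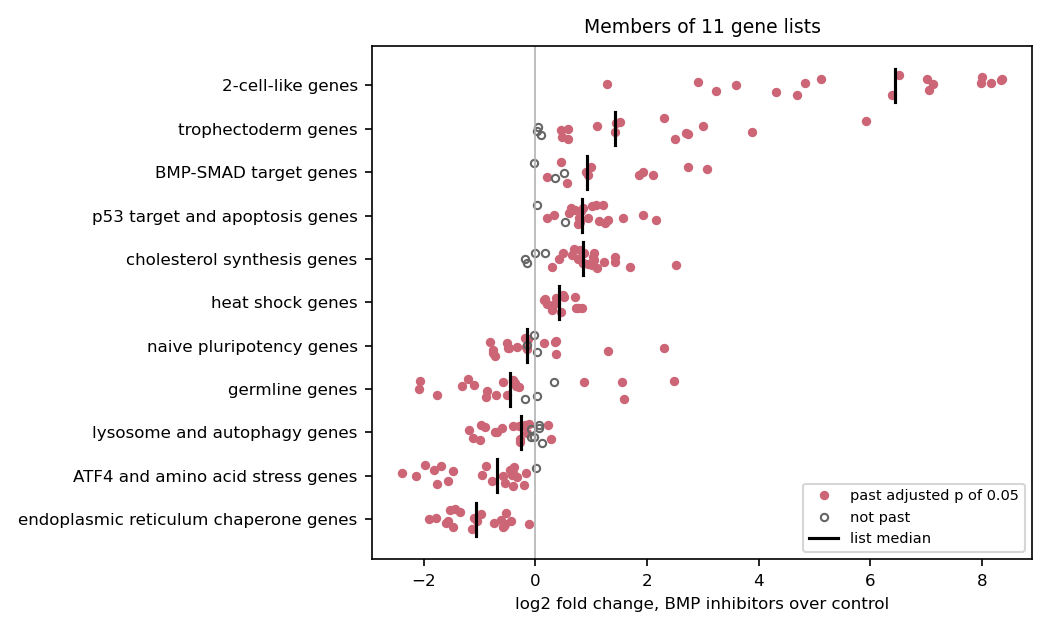
Log2 fold change (x axis, BMP inhibitors over control) of each tested member of 11 gene lists (y axis). Filled points passed an adjusted p of 0.05, open points did not, black lines are list medians, and genes with 0 control counts are drawn at their lower bound; medians ran from 6.45 for 2-cell-like genes to -1.07 for endoplasmic reticulum chaperones.

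Stress-response programmes moved in opposite directions. All 20 endoplasmic reticulum chaperone genes fell (median -1.07, camera adjusted p = 1.4e-09; adjusted p = 0.18 with an estimated correlation). Hspa5, the main chaperone of this compartment, went from 1323 ± 43.6 to 490 ± 6.44 CPM (SD, n = 3; log2 fold change -1.43, SE 0.04), and Creld2 from 264 ± 3.18 to 70.3 ± 1.20 CPM. Hsp90b1 and Dnajc3 had log2 fold changes of -1.47 and -1.52. Of 22 genes of the ATF4 and amino acid stress list 21 fell and 0 rose (median -0.68, camera adjusted p = 5.2e-08; adjusted p = 0.18 with an estimated correlation). Among them Ddit3, which encodes the stress factor CHOP, went from 91.9 ± 0.407 to 23.5 ± 4.08 CPM, and Nupr1, Pck2 and Stc2 had log2 fold changes of -1.82, -1.57 and -2.14. By contrast 20 of 22 p53 target and apoptosis genes rose and 0 fell (median 0.84, camera adjusted p = 1.3e-08; adjusted p = 0.18 with an estimated correlation). Pmaip1, Mdm2, Phlda3 and Plk2 rose by 1.93, 1.25, 1.21 and 1.57. All 14 heat shock genes rose, by a median of 0.42 (camera adjusted p = 0.00023; adjusted p = 0.18 with an estimated correlation), Hsph1 and Hspb1 by 0.83 and 0.77. Hsp90b1 and Ddit3 overlap other genes on the same strand, and Pck2 overlaps an antisense gene.

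**Figure D3:**
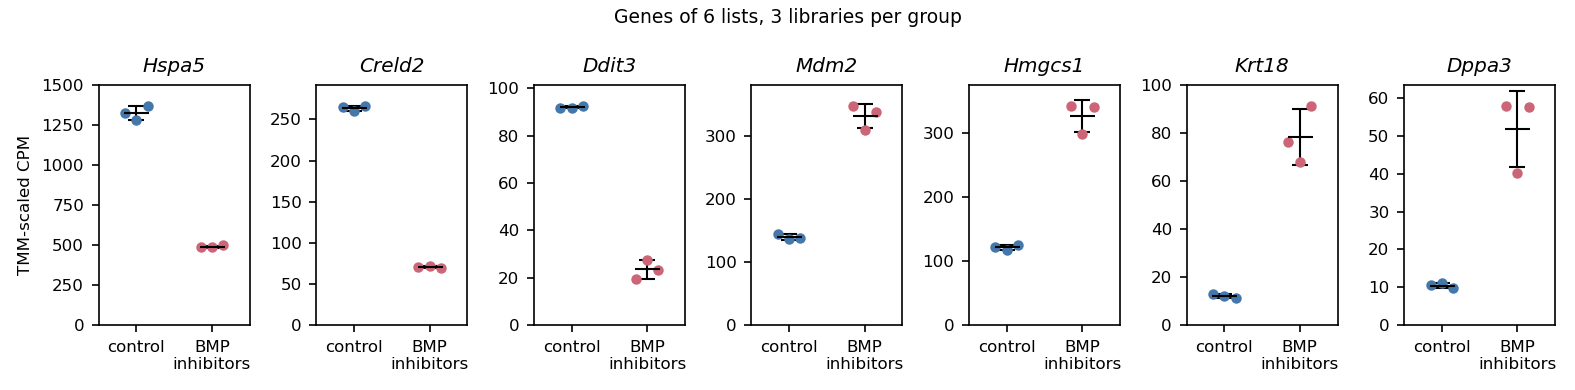
TMM-scaled counts (CPM, linear axes from 0) of Hspa5, Creld2, Ddit3, Mdm2, Hmgcs1, Krt18 and Dppa3 in control and BMP-inhibited libraries. Points are libraries and black bars are mean ± SD over 3 libraries; Hspa5 fell from 1323 to 490 CPM and Krt18 rose from 12.03 to 78.3 CPM, with no overlap between groups.

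Genes of lipid and sugar metabolism were mostly higher. In the cholesterol synthesis pathway 21 of 25 genes rose and 0 fell, or 21 and 1 adjusted over the list alone (median 0.85, camera adjusted p = 1.7e-07; adjusted p = 0.18 with an estimated correlation). Hmgcs1 rose from 122 ± 3.98 to 327 ± 25.1 CPM, and Idi1 rose by 1.69. Fallers of this pathway numbered 2 with library totals only and without BMP-inhibited replicate 2, and 1 with upper-quartile factors, after thinning and without control replicate 1. Fatty acid genes had 13 risers and 2 fallers among 20 (camera adjusted p = 0.021; adjusted p = 0.18 with an estimated correlation), Fasn, Elovl6, Acadvl and Srebf1 rising by 0.84, 1.12, 1.22 and 0.73. With library totals only, or without BMP-inhibited replicate 2, 4 fatty acid genes fell. Glycolysis genes had 13 higher and 3 lower of 19 (camera adjusted p = 0.004; adjusted p = 0.37 with an estimated correlation), with Ldha, Pfkl, Eno1 and Pkm higher by 1.29, 1.15, 0.97 and 0.72. In the hypoxia list 13 rose and 4 fell of 19 (camera adjusted p = 0.037; adjusted p = 0.28 with an estimated correlation), and its member with the smallest p, the angiogenic factor gene Vegfa, fell from 122 ± 2.33 to 32.1 ± 2.15 CPM. Egln3, Kdm3a and Bnip3l rose by 0.93, 0.46 and 0.45. The hypoxia call was lost without BMP-inhibited replicate 3 (adjusted p = 0.05). Nuclear-encoded respiratory chain genes had 9 higher and 9 lower of 24, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.97), with Cox7a2, Uqcrfs1 and Atp5b at 0.52, 0.48 and 0.29 and Ndufa2 at -0.45. Their median was -0.02 and their mean 0.02. Hmgcs1, Idi1, Acadvl, Elovl6 and Ndufa2 overlap antisense genes, and Srebf1 and Pkm overlap genes on the same strand.

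Among other signalling pathways, ERK response genes were mostly higher, in a medium that held a MEK inhibitor in both groups. Of 18 tested, 11 rose and 3 fell (median 0.69, camera adjusted p = 0.017; adjusted p = 0.28 with an estimated correlation). Myc and Phlda1 rose by 2.65 and 2.74, Spry4 by 1.76 and Etv5 by 1.15, and 5 members fell with library totals only. Genes responding to TGF-beta, activin and nodal had 7 higher and 6 lower of 15, with a median of 0.12 and a mean of -0.02 (camera adjusted p = 0.81). Ccn2 rose by 1.72, while Tgfbi and Tgif1 had log2 fold changes of -1.90 and -0.62. LIF-STAT3 genes had 8 higher and 6 lower of 15 (camera adjusted p = 0.52), with Bcl3 at 0.76 and Socs2 and Pim3 at -0.56 and -0.56. WNT response genes had 7 higher and 3 lower of 13 (camera adjusted p = 0.037; adjusted p = 0.18 with an estimated correlation, and 0.085 with the stricter count filter), Axin2, Notum and Apcdd1 rising by 1.90, 1.11 and 1.01. YAP response genes had 8 higher and 1 lower of 13, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.18 with an estimated correlation), Ccn1, Ptpn14 and Amotl2 rising by 2.03, 1.02 and 0.49. With library totals only or upper-quartile factors 2 of them were lower. NOTCH response genes had 3 higher and 3 lower of 11 (camera adjusted p = 0.81), with Jag1 and Notch1 at 0.86 and 0.63 and Hes1 and Dtx1 at -1.01 and -0.93. Phlda1, Ccn2, Bcl3, Axin2, Notum, Ptpn14 and Notch1 overlap antisense genes.

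Adhesion, matrix and epithelial-mesenchymal genes had 14 higher and 6 lower of 25 (camera adjusted p = 0.027; adjusted p = 0.18 with an estimated correlation). Their median was 0.27 and their mean 0.90. The largest rise on this list was that of Acta2, which had 0 control counts. Acta2 and Tagln are also on the fibroblast list below. S100a6, Lgals1, Cdh1 and Itgb1 rose by 2.42, 1.08, 0.59 and 0.55, so that both the epithelial cadherin gene and the mesenchyme-associated Lgals1 were higher. Markers of fibroblasts, the usual feeder cells, had 5 higher and 3 lower of 12 (camera adjusted p = 0.43). With no count filter this list passed, upward (adjusted p = 0.044). Acta2 had 0 and 226 counts, at least 82.2-fold higher, while Tagln, Col1a1 and Mmp2 rose by 2.81, 1.43 and 0.65. Tagln overlaps an antisense gene.

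Cell-cycle genes changed by small amounts. G2/M genes had 13 lower and 1 higher of 22 (median -0.16, camera adjusted p = 0.025; adjusted p = 0.18 with an estimated correlation), Ube2c, Cdk1, Hmmr and Top2a having log2 fold changes of -0.54, -0.34, -0.30 and -0.26. Without BMP-inhibited replicate 2, 2 were higher. S phase genes had 9 higher and 4 lower of 22 (camera adjusted p = 0.27), with Rrm1, Ccne2 and Slbp at 0.53, 0.71 and 0.37 and Pola1 at -0.49. Ube2c, Ccne2 and Slbp overlap antisense genes and Top2a a gene on the same strand.

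Some transcripts that can reflect RNA quality or selection differed between the groups too. Mitochondrially encoded genes took 0.973 ± 0.038% of control counts and 1.59 ± 0.076% of BMP-inhibited counts (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 allows, two-sided). Of 18 tested, 13 rose and 0 fell (camera adjusted p = 0.00027; adjusted p = 0.18 with an estimated correlation), mt-Nd1, mt-Nd2, mt-Nd5 and mt-Nd4 rising by 0.90, 0.88, 0.83 and 0.76. With limma-voom, or without BMP-inhibited replicate 2, 1 fell. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had 18 higher and 2 lower of 45, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.0048; adjusted p = 0.18 with an estimated correlation). They took 0.00498% of control counts and 0.00786% of BMP-inhibited counts (means, exact permutation p = 0.1). Hist1h1c, Hist1h4i and Hist1h2ae rose by 1.24, 1.09 and 1.68, while Hist3h2a was at -2.19. With the stricter count filter, without control replicate 2 or 3 and without BMP-inhibited replicate 1, 1 was lower. Ribosomal protein genes had 42 higher and 7 lower of 83 (median 0.12, camera adjusted p = 0.0073; adjusted p = 0.70 with an estimated correlation), Rpl13a, Rpl15 and Rpl37a rising by 0.50, 0.39 and 0.44 and Rpl39l by 1.67. That call was lost with library totals only (adjusted p = 0.053, 11 lower) and without control replicate 2 (0.069). The ribosomal protein share of counts overlapped between the groups, at 4.84 ± 0.14% in controls and 5.01 ± 0.11% in BMP-inhibited libraries (exact permutation p = 0.2). Several of these genes, among them mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, Hist3h2a, Hist1h2ae, Rpl13a and Rpl15, overlap other genes.

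Across the 37 lists, 22 passed with the preset correlation, 17 upward and 5 downward. With an estimated correlation 0 passed, at 6 libraries, the smallest adjusted p being 0.18. Lists with an unadjusted p from 0.0089 (cholesterol synthesis) to 0.083 (mitochondrially encoded) in that test share this adjusted value, so it does not rank them. The directional fry test called 31. It asks whether a list moved at all, not whether it moved further than other genes. With 64.2% of tested genes called, it cannot show that a list stood out.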

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

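The tests of the patterns below were chosen after the results had been seen, apart from the count of other splits. Outside the gene counts, 1.25 ± 0.01% of reads were ambiguous between genes in BMP-inhibited libraries and 1.22 ± 0.01% in controls, drawing attention as a signal above the controls in data not otherwise used. Unaligned reads were 2.77 ± 0.25% against 2.23 ± 0.13% (SD, n = 3), for the same reason. No explanation was tested for either.

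All 18 tested 2-cell-like genes rose. For 4 members, Tmem92, Spz1, Arg2 and Pramel6, no near-identical copy was found, so reads divided differently among copies do not apply to them, and their median log2 fold change of 4.22 tests nothing about that explanation. For the 14 members with copies, counts summed over each member and its copies rose by a log2 fold over 1 in 13 cases, 10.24 for the Zscan4 family. The exception was Gm2022, at 0.36, where 20 summed genes held 21256 control counts, so copies stay open for the group of members with copies taken as a whole. The 13 cases are not independent. All Zscan4 members share the same sum, as do Usp17la and Usp17lc, and the sums of Tcstv1 and Tcstv3 overlap. Whether a few cells or many carried these transcripts, and whether noggin or dorsomorphin was responsible, was not tested.

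Endoplasmic reticulum chaperone and ATF4 genes fell, with a joint median log2 fold change of -0.92. With offsets over GC content and length, known for 99.9% of tested genes, it was -0.91, which argues against such bias as the whole cause. With library totals only it was -0.98. That scaling moved the median of all tested genes only from -0.003 to -0.062, too little to remove the fall. The fall thus does not rest on the choice between these scalings, but other scaling errors cannot be judged from it. A response of the cells to the inhibitors remains a hypothesis, consistent with these values and found on the same data. Effects of culture density or medium age were not tested.

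BMP-SMAD target genes rose with BMP inhibitors. A single mislabelled library is argued against, since the highest correlation between groups, 0.9591, lay below the lowest within a group, 0.9914. Exchanged labels of the whole groups cannot be told apart from a true rise, because no transcript marks the added inhibitors and Id1 rose by 2.11 under the labels as given. Trophectoderm-like cells may contribute: without Gata2, Gata3, Dlx3 and Msx2 the other 10 tested targets kept a median of 0.54, which neither excludes nor requires such cells. Abundant trophectoderm keratins reached 78.3 CPM for Krt18 and 89.96 CPM for Krt8. The trophectoderm genes that did not pass, named after their values were seen, were Eomes (8.95 and 9.20 CPM in control and BMP-inhibited cells, log2 fold change 0.04), Tfap2c (128 and 137 CPM, 0.10) and Ets2 (28.8 and 29.8 CPM, 0.05). Tfap2c passed without BMP-inhibited replicate 2 (0.155, adjusted p = 0.00261). With library totals only, Eomes and Ets2 were at -0.019 and -0.011, and Eomes at -0.007 without control replicate 1. Eomes overlaps an antisense gene. No profile of trophectoderm cells was at hand to say how far these genes would rise, so such cells stay open.

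The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 10236 genes and the highest of the others 0, so 1 of 10 splits gave as many. For lists the real split called 22 and the highest other 14, again 1 of 10. Each other split still sets 2 libraries of one group against 2 of the other, so part of the group difference stays in it. It also mixes both groups on each side, so the group difference widens the spread within a side and holds gene calls down. The 0 is therefore not a rate of false calls. These splits still called 8 to 14 lists.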

How the results depend on the processing

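The number of changed genes ranged from 9356 to 10890 across the other tests, scalings, filters, offsets, depth and gene class, apart from those named next. Without genes whose exons overlap another gene 6556 genes were called (3319 higher, 3237 lower, 1644 at least 2-fold), where 10362 rather than 15951 were tested. With an added 2-fold threshold 2467 were called (1277 higher, 1190 lower), and this count was 1666 with the stricter count filter, 3230 with no filter and 1910 for protein-coding genes only. Leaving out 1 library gave 9267 to 10680 calls, 4670 to 5436 higher, 4597 to 5244 lower and 2490 to 2773 changed at least 2-fold, and 422 to 1205 of the main calls were lost with 0 changing sign. With GC content and length offsets 8 main calls changed sign, 0 of them still called, and likewise 8 with the replicate block as well. DESeq2 shared 9817 of the 10236 calls and limma-voom 10160. Library totals only moved the share of higher calls from 50.6% to 44.4%. Replicate numbers did not pair libraries, as deviations of same-numbered libraries correlated at -0.044 to 0.029 and 2 of 6 libraries correlated best with their own number. The replicate block called 10210 genes and 21 lists, and 10372 genes and 21 lists with GC content and length offsets. Under the block Pou5f1 passed (adjusted p = 0.0331) and the hypoxia list did not (0.057, and 0.051 with the offsets as well), and 2 rather than 1 mesoderm genes fell.

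Of 37 lists, 22 passed, 21 to 24 under other scalings, filters and offsets and 21 to 22 without 1 library. With an estimated correlation 0 passed. Fry called 31, but it does not compare a list with other genes, so these counts answer different questions. Why the estimated correlation left no list past the threshold was not tested. Lists far from the threshold changed sign. Neuroectoderm had an adjusted p of 0.88 with library totals only, 0.54 with no filter and 0.54 to 0.95 without 1 library, changing sign without any library but BMP-inhibited replicate 2. The respiratory chain had 0.72 by fry and 0.72 to 0.98 without 1 library, changing sign without BMP-inhibited replicates 1 and 3. NOTCH had 0.63 to 0.95, changing sign without BMP-inhibited replicate 2. The cause was not tested. Of 166 named genes, 0 changed direction and 2, Id3 and Pou5f1, changed their call. Of 19 others named outside the rule, Tfap2c (0.155, adjusted p = 0.00261) and Ahrr (-0.825, 0.0259) passed without BMP-inhibited replicate 2. Eomes and Ets2, near 0, changed sign with library totals only (-0.019 and -0.011), and Eomes ranged from -0.007 to 0.062 without 1 library. In a test added after the data were seen, the mesoderm list did not pass without the members it shares with the trophectoderm list (adjusted p = 0.057). Depth limits genes with a few counts, where folds are bounds or have wide intervals.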

Other observations

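The list of actin and serum response factor genes, and its test, were set before its members' values were seen; the chromosome test and the aryl hydrocarbon receptor genes were chosen after.

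Of 23 imprinted genes tested, 10 rose, 6 fell and 7 did not pass, or 11 rose and 6 fell adjusted over the list alone. At least 2-fold changes were 4 in each direction (median 0.03, or -0.03 with library totals only, camera adjusted p = 0.72). H19 and Cdkn1c rose by 3.37 and 3.06, while Grb10 went from 395 ± 0.625 to 102 ± 6.48 CPM (log2 fold change -1.95) and Meg3 had a log2 fold change of -2.09. Lysosome and autophagy genes had 16 lower and 2 higher of 24 (camera adjusted p = 0.0036; adjusted p = 0.28 with an estimated correlation), Lamp2, Ctsl, Hexa and Atp6v0d1 at -1.18, -1.11, -0.97 and -0.70. Interferon response genes had 8 higher and 2 lower of 13, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.13), with Bst2, Irf1, Oas1a and Tap1 at 0.81, 0.68, 1.25 and 0.93. With no count filter the interferon list passed, upward (adjusted p = 0.0031), with 13 higher, and with the stricter filter 5 were higher. H19, Meg3 and Ctsl overlap genes on the same strand, and Cdkn1c, Hexa, Irf1 and Tap1 overlap antisense genes.

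Besides Cyp1a1, Cyp1b1 rose by 3.95, with only 6 counts in the control libraries together and 90 in the BMP-inhibited ones. Nqo1 rose by 0.92, Tiparp by 0.34 and Ahr by 0.42 (adjusted p = 0.0209 for Ahr). Ahrr (-0.55, adjusted p = 0.102) and Aldh3a1 (-0.23, adjusted p = 0.234) did not pass. Tiparp and Ahr overlap antisense genes. Ahrr passed without BMP-inhibited replicate 2 (-0.825, adjusted p = 0.0259).

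Acta2, Tagln and Myl9, contractile genes, rose, Myl9 by 4.31. A hypothesis was that a wider actin and serum response factor programme may have risen. Of 16 other tested genes of that kind 13 rose, among them Srf (0.99), Cnn2 (1.64) and Actb (0.55), and 1, Actn1, fell (-0.30), with a median of 0.80. Camera gave an unadjusted p of 5.4e-05 with the preset correlation and 0.074 with an estimated one, short of the bound set beforehand, so the hypothesis stays open.

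Gain or loss of a whole chromosome in 1 group was examined as a source of the many changed genes. Among the autosomes and chromosome X, for genes with a mean log2 CPM over 3, the largest absolute median log2 fold change was 0.064. It was that of chromosome 8 over 554 genes, which argues against such a change of these chromosomes in most cells.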
